A study of Neocallimastix californiae and Anaeromyces robustus with 43 samples.

How the data were processed

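Messenger RNA abundance was measured by RNA sequencing in 2 anaerobic gut fungi, early-branching fungi that live in the digestive tract of plant-eating mammals and break down plant cell walls. Neocallimastix californiae, labelled G1, gave 23 libraries over 8 carbon sources, and Anaeromyces robustus, labelled S4, gave 20 libraries over 7. Per the labels' protocols, cultures of about 10 ml of Medium C were grown at 39 °C to the middle of logarithmic growth, judged by a gas pressure of at least 5 psi. RNA was taken with a Qiagen RNeasy Mini kit, libraries were made with the Illumina TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps strand, and the design text names an Illumina NextSeq.

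The authors deposited, for each fungus, 1 table of expected counts and 1 table of TPM, with a value for each transcript in each library. The expected counts are estimates from RSEM, per the submitters' processing notes, which name no version. Expected counts divide the reads that fit several transcripts between them, and 10.2% of the values of N. californiae and 10.4% of those of A. robustus were not whole numbers (tolerance 1e-09). The deposited TPM values correct the same estimates for transcript length and sum to 1000000 in each library. The aligner under RSEM, the reference transcripts and any read filter are not given in the sources used here. The tables hold 29649 transcripts from 27671 loci for N. californiae and 17127 transcripts from 16038 loci for A. robustus. All 86 columns matched 1 library each by its title.

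The transcript identifiers combine a locus number, a version number and a number after the letters rpkm, and 824 identifiers of N. californiae and 506 of A. robustus end in PRE. The meaning of the last 2 parts is not given in the sources used here. The files do not pair the identifiers with gene names or functions, so no function is stated for any transcript. The gene lists fixed beforehand (cellulases and hemicellulases, beta-glucosidases, esterases, starch enzymes, carbohydrate-binding and cellulosome proteins and others) could not be matched and were not tested. In N. californiae 1671 loci and in A. robustus 892 loci have more than 1 version. Versions of a locus share reads, so the value of a single version is uncertain where its sister versions are expressed.

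Samples were grouped by fungus and carbon source as the labels give them, with 3 libraries per group except 2 for N. californiae on switchgrass and 2 for A. robustus on corn stover. Replicates of a group were compared by a chi-square statistic of their counts. It lay between 3.87 and 34.3 per degree of freedom in N. californiae and between 18.8 and 1882 in A. robustus, so no 2 libraries agreed within sampling noise. The labels do not say whether the replicates came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical in part.

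Expected counts were rounded to whole numbers. The 2 fungi were analysed apart. Transcripts were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3 with a minimum count of 10 and a minimum total of 15, which left 14800 transcripts of N. californiae and 10316 of A. robustus, holding 99.8% and 99.9% of all counts. Libraries were scaled by TMM, whose factors ran from 0.64 to 1.43 in N. californiae and from 0.18 to 1.97 in A. robustus. A quasi-likelihood model with robust trended dispersion was fitted to all libraries of a fungus together, with 1 mean per carbon source, because groups of 2 or 3 give a poor estimate of the spread alone. The biological coefficient of variation was 0.29 in N. californiae and 0.39 in A. robustus. Contrasts were tested by edgeR's quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg within each comparison. A transcript was called at an adjusted p under 0.05, without a fold threshold. Each carbon source was compared with glucose. Cellobiose was also compared with maltose, Avicel with cellobiose, the mean of the 3 grasses (reed canary grass, switchgrass and corn stover) with Avicel, and alfalfa stems with that mean. CPM values below are counts per 1000000 after TMM scaling, and errors of log2 fold changes are standard errors.

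Transcripts were named by a rule set before the data were examined. For each comparison the 2 called transcripts with the largest positive and the 2 with the largest negative log2 fold change were eligible, if they reached a mean of 10 CPM in the higher group and the libraries of the groups did not overlap. Not every eligible transcript is printed. The folds of transcripts without counts in 1 group are lower bounds, taken against 3 counts over all libraries of that group, and cover counting error only.

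The alternatives set before the data were examined were DESeq2 1.42.0, DESeq2 size factors inside edgeR, no filter on low counts, a threshold of 2-fold, the replicate number as a block, only the compared groups in the fit, each library left out in turn, and TPM in place of counts for shares of abundance. Scaling by library size alone, counts summed per locus, and fits without single libraries that stood apart were chosen after seeing the data. The block and its check are described with the other alternatives. Because all comparisons with glucose use the same glucose libraries, overlaps of calls and correlations of fold changes were set beside 10 simulations of unchanged groups and beside the overlap of independent lists. The simulations drew the glucose libraries anew as well, so they do not carry the deviations of the real ones. The 3 glucose libraries cannot be split into separate groups of 2, so part of any excess may come from the shared controls.

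The test was checked on simulated counts for Avicel against glucose, drawn with the transcripts' fitted dispersions and the real library sizes. Every library was drawn from the glucose mean, and 200 transcripts with a mean of at least 1 CPM were changed on Avicel. In N. californiae, over 14800 transcripts, it recovered 17% of 2-fold and 70% of 4-fold changes. In A. robustus, over 10316 transcripts, it recovered 2% of 2-fold and 53% of 4-fold changes. Each simulation called 1 unchanged transcript, and no changed transcript was called in the wrong direction. Apart from the changed transcripts, which rose and fell equally often, all simulated libraries had the same composition. This check therefore does not cover errors from scaling or from libraries that stand apart. The 100 most abundant transcripts of a fungus were those with the highest mean CPM over its libraries, and the same 100 were kept under the alternatives. To compare how many transcripts were detected, each library was thinned without replacement to 1500000 counts. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.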

Results

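The data cover the transcriptomes of 2 anaerobic gut fungi, N. californiae (G1) and A. robustus (S4), during exponential growth on single carbon sources. The design asks how the carbon source changes transcript abundance. Glucose is the simplest of the sugars. Maltose and cellobiose are disaccharides of glucose, joined by the alpha linkage of starch and the beta linkage of cellulose. Avicel is microcrystalline cellulose. Corn stover, switchgrass and reed canary grass are grass biomass, which holds hemicellulose and lignin beside cellulose, and alfalfa stems are legume biomass, given to N. californiae only. The 43 libraries held 2583040 to 10816458 expected counts (median 4560473) in N. californiae and 1946186 to 31742828 (median 15176293) in A. robustus. The lowest total of A. robustus belonged to maltose replicate 3.

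Libraries of 1 carbon source resembled each other more than those of other carbon sources in some groups but not in others. By the median rank correlation, maltose, cellobiose and switchgrass libraries of N. californiae were closer to those of another carbon source. So were maltose, Avicel and corn stover libraries of A. robustus. The remaining groups were closest within themselves. In N. californiae the rank correlation between replicates across transcripts ranged from 0.96 to 0.97 on Avicel, from 0.93 to 0.97 on glucose and from 0.91 to 0.95 on alfalfa stems. Cellobiose replicates 1 and 2 correlated at 0.96, but replicate 3 correlated at only 0.88 to 0.89 with them at 0.91 with each Avicel library, at 0.87 to 0.92 with the alfalfa stems libraries and at 0.89 with glucose replicate 3. In A. robustus libraries of different grasses were close to each other: reed canary grass libraries correlated at 0.97 to 0.98 with each other and at 0.96 to 0.98 with corn stover libraries. Avicel replicate 1 stood apart from the other 2 Avicel libraries, at 0.87 to 0.88 against 0.97 between those. Maltose replicate 3 of A. robustus correlated at only 0.65 to 0.66 with the other 2 maltose libraries. A single transcript, Locus13069v1rpkm0.51, singled out after its values were seen, held 42.5% of the counts of that library.

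In N. californiae 9254 of 14800 tested transcripts differed between carbon sources, and in A. robustus 6563 of 10316 did (edgeR quasi-likelihood test over all substrates). The number of calls against glucose was smallest on maltose and far larger on Avicel and on the grasses. Scaling mattered for the balance of higher and lower calls. With library size alone in place of TMM the median log2 fold change of all transcripts against glucose moved by between -0.68 and 0.02 in N. californiae and by between -0.81 and 1.04 in A. robustus, so directions below are relative to the TMM scale, and the alternative split is given where it moved by over 10 percentage points. Which side held more calls turned under at least 1 alternative in 8 comparisons of N. californiae (Avicel, each grass and alfalfa stems against glucose, cellobiose against maltose, the grasses against Avicel, and alfalfa stems against the grasses) and in 1 of A. robustus (Avicel against glucose).

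**Figure D1:**
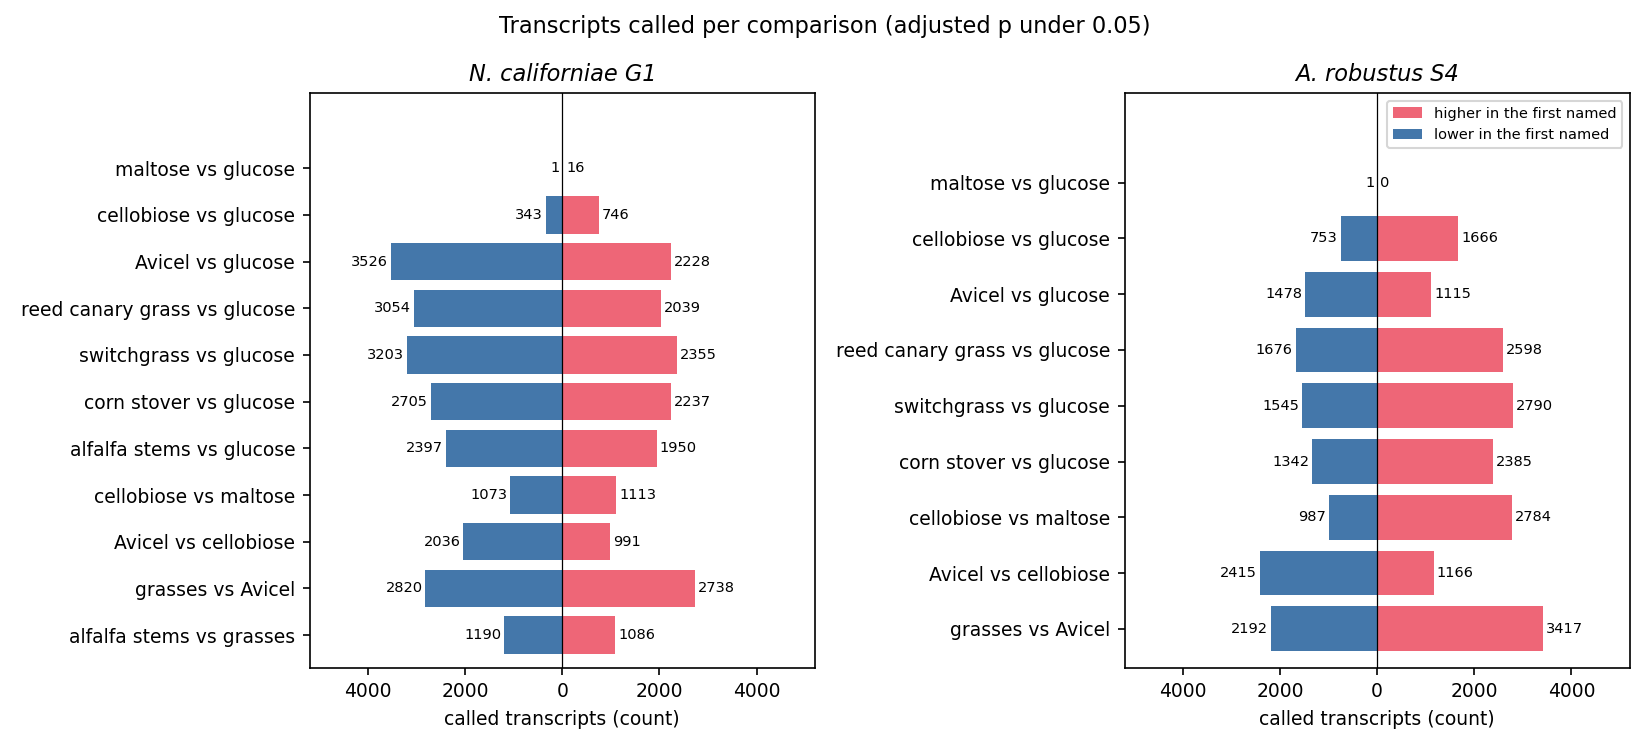
Transcripts called at an adjusted p under 0.05 in each comparison, as horizontal bars of counts for N. californiae (left) and A. robustus (right). Red bars to the right count transcripts higher, and blue bars to the left transcripts lower, in the carbon source named first. Maltose gave 16 higher and 1 lower in N. californiae and 0 higher and 1 lower in A. robustus, while the grasses against Avicel gave 2738 and 2820, and 3417 and 2192.

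Maltose changed little in N. californiae. Locus6802v1rpkm6.59 rose from 16.4 ± 2.94 CPM on glucose to 77.8 ± 27.6 CPM on maltose (SD, n = 3 each), a log2 fold change of 2.25 ± 0.33 (edgeR adjusted p = 0.0115). Locus868v1rpkm152.50 rose from 7.17 ± 3.12 to 27.5 ± 4.62 CPM (1.91 ± 0.32, edgeR adjusted p = 0.0198). Both stood high on the grasses as well, at 91.9 ± 19.7 and 299.5 ± 68.9 CPM on reed canary grass. The only transcript called lower was Locus990v1rpkm126.74, at 50.4 ± 10.3 against 116 ± 6.25 CPM (-1.20 ± 0.22, edgeR adjusted p = 0.0276). In all 16 transcripts were called higher and 1 lower, and 626 passed an unadjusted p under 0.05. The count depended on single libraries: it was 0 without glucose replicate 2, 2 without glucose replicate 1, 4 and 8 without maltose replicate 2 and 3, 30 without cellobiose replicate 3 in the fit and 51 without maltose replicate 1. It was 72 with DESeq2 (58 higher, 14 lower), 63 with library size alone (51 higher, 12 lower) and 0 with only the 6 glucose and maltose libraries in the fit, where the adjusted p of Locus6802v1rpkm6.59 was 0.147 and that of the other 2 named transcripts 0.32.

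Cellobiose, which holds the same sugar units as maltose, gave a larger and clearly different response in N. californiae. Locus2437v1rpkm34.26 rose from 0.482 ± 0.276 CPM on glucose to 71.7 ± 33.3 CPM on cellobiose (log2 fold change 7.41 ± 0.59, edgeR adjusted p = 6.9e-08), and it was as high on Avicel (81.3 ± 8.71 CPM). Locus3634v1rpkm18.60 had no counts on glucose or maltose and 14.6 ± 10.02 CPM on cellobiose, at least 117-fold higher than on glucose. Locus1619v1rpkm61.70 fell from 219 ± 41.1 CPM on glucose to 1.90 ± 0.942 CPM on cellobiose (-6.91 ± 0.44, edgeR adjusted p = 9.04e-09), and stood at 410 ± 92.5 CPM on maltose and 574 ± 193 CPM on reed canary grass. Locus2451v1rpkm34.06 was at 11.5 ± 4.34 CPM on glucose and 0.154 ± 0.0565 CPM on cellobiose, and at 1116 ± 248 CPM on reed canary grass. Against glucose 746 transcripts were called higher and 343 lower. The split was 574 and 469 with library size alone. The count was 633 without glucose replicate 1, 564 without glucose replicate 2 and 526 with only the cellobiose and glucose libraries in the fit.

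Set directly against maltose, cellobiose raised 1113 transcripts and lowered 1073. Locus881v1rpkm148.44 fell from 399 ± 83.7 CPM on maltose to 2.67 ± 1.88 CPM on cellobiose (log2 fold change -7.31 ± 0.42, edgeR adjusted p = 8.81e-10), and Locus1619v1rpkm61.70 fell by 7.82 ± 0.45 on the log2 scale. The split was 833 higher and 1524 lower with library size alone, and 1289 and 1908 with the replicate block. The total was 1365 without maltose replicate 1, 1144 without maltose replicate 2 and 1334 without cellobiose replicate 2. Of the calls against glucose, maltose and cellobiose shared 5 transcripts in the same direction and had 7 in opposite directions, where independent lists would share 0.81 higher.

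On Avicel, the insoluble cellulose, N. californiae changed transcripts in both directions. Locus8103v1rpkm4.73 rose from 0.154 ± 0.139 CPM on glucose to 299.3 ± 17.2 CPM on Avicel (log2 fold change 10.37 ± 0.64, edgeR adjusted p = 5.47e-10). It was near absent on the grasses, at 0.67 to 1.85 CPM on average, and reached 18.1 ± 9.76 CPM on alfalfa stems. Locus3634v1rpkm18.60 stood at 30.03 ± 10.7 CPM, at least 241-fold higher than on glucose. Locus5951v2rpkm2.12 had 25.7 ± 16.8 CPM on glucose and no counts on Avicel, at least 127-fold lower. In total 2228 transcripts were called higher and 3526 lower. Of these, 312 rose and 1416 fell by at least 8-fold. The split was 1002 and 5340 with library size alone, 3169 and 3065 with counts summed per locus and 2715 and 2650 without Avicel replicate 2, so the larger side was not stable.

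Against cellobiose, the soluble building block of cellulose, Avicel raised 991 transcripts and lowered 2036 in N. californiae. Locus11091v2rpkm0.72 rose from 0.258 ± 0.311 CPM on cellobiose to 64.7 ± 6.30 CPM on Avicel (log2 fold change 8.22 ± 0.66, edgeR adjusted p = 1.54e-07). Locus15259v1rpkm1.08 had 13.6 ± 2.21 CPM on cellobiose and no counts on Avicel, at least 67.2-fold lower, but this call was lost without the filter on low counts (edgeR adjusted p = 0.0723). Avicel and cellobiose shared 602 transcripts called higher and 246 called lower against glucose, where independent lists would share 112 and 81.7, and 33 went in opposite directions. Without cellobiose replicate 3, the library that stood apart from its group, Avicel against cellobiose gave 3810 calls in place of 3027. The total was 1515 without cellobiose replicate 1, and 1888 and 1600 without Avicel replicate 1 and 3. The split with library size alone was 438 higher and 3210 lower.

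The grasses switched on transcripts that were near absent on the sugars in N. californiae. Locus1317v1rpkm83.52 had no counts on glucose or cellobiose and reached 242 ± 88.9 CPM on reed canary grass (n = 3), 473 ± 198 CPM on switchgrass (n = 2) and 354 ± 107 CPM on corn stover (n = 3). These levels were at least 1942-fold, 3802-fold and 2845-fold higher than on glucose, and alfalfa stems gave only 0.76 ± 0.693 CPM. Locus2090v1rpkm42.44 had 2 counts over the 3 glucose libraries (0.126 ± 0.218 CPM) and stood at 1511 ± 571, 2864 ± 1182 and 2416 ± 653 CPM on the grasses in the same order, and at 39.8 ± 5.03 CPM on Avicel. Among the transcripts that fell, Locus494v1rpkm365.45 went from 36.4 ± 15.02 CPM on glucose to no counts on reed canary grass, at least 135-fold lower, and was high on cellobiose (280 ± 103 CPM), Avicel (209 ± 12.2 CPM) and alfalfa stems (284 ± 23.2 CPM). Locus2247v1rpkm38.34 had 114 ± 52.8 CPM on glucose and no counts on switchgrass, at least 221-fold lower. Locus7606v1rpkm5.34 had 15.3 ± 2.92 CPM on glucose and no counts on corn stover, at least 59.5-fold lower.

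Reed canary grass raised 2039 and lowered 3054 transcripts against glucose in N. californiae, switchgrass raised 2355 and lowered 3203, and corn stover raised 2237 and lowered 2705. With library size alone the splits were 1172 and 5120, 1280 and 6449, and 1233 and 6568. The larger side turned with counts summed per locus, to 2591 and 2471, 2811 and 2507, and 2625 and 1982. With DESeq2, switchgrass gave 2728 higher and 2472 lower and corn stover 2488 and 2224. Without the filter on low counts corn stover gave 2326 and 1819, and without its replicate 1 reed canary grass gave 2467 and 2051. Without glucose replicate 2 reed canary grass gave 3379 calls, and switchgrass gave 3588 without its replicate 1 (2137 higher, 1451 lower) and 3326 without its replicate 2 (2263 higher, 1063 lower), so its balance turned. Reed canary grass shared 1683 transcripts called higher and 2279 called lower with switchgrass, where independent lists would share 324 and 661, and only 5 went in opposite directions. With corn stover it shared 1624 and 1621, where independent lists would share 308 and 558, and 2 were opposite. The correlation of log2 fold changes across transcripts was 0.82 and 0.79, where simulated unchanged groups that shared simulated glucose libraries gave 0.41 and 0.47. The covariance was 2.64 and 1.96 against a simulated 0.18 in both. Transcripts are not independent replicates.

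Alfalfa stems shared much of the grass response in N. californiae, but some transcripts differed widely. Locus256v1rpkm964.71 stood at 2093 ± 290 CPM on alfalfa stems, 1390 ± 143 CPM on Avicel and 532 ± 208 CPM on cellobiose, against 0.581 ± 0.469 CPM over the 8 grass libraries. The log2 fold change of alfalfa stems against the grasses was 11.96 ± 0.39 (edgeR adjusted p = 2.06e-14), and that of the grasses against Avicel was -11.37 ± 0.39 (edgeR adjusted p = 4.4e-14). Locus494v1rpkm365.45 rose by 9.27 ± 0.39 on the log2 scale. Locus4401v1rpkm13.76 had 69.2 ± 35.2 CPM on the grasses and no counts on alfalfa stems, at least 245-fold lower. Alfalfa stems against the grasses gave 1086 higher and 1190 lower, but 2260 and 691 with library size alone, so the balance depends on the scaling. The total was 1417 and 1278 without alfalfa stems replicate 1 and 3.

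Against glucose, alfalfa stems raised 1950 and lowered 2397 transcripts in N. californiae. Locus10268v1rpkm2.91 had no counts on glucose and 24.8 ± 6.93 CPM on alfalfa stems, at least 199.7-fold higher. Locus3239v2rpkm12.96 had 10.1 ± 3.35 CPM on glucose and no counts on alfalfa stems, at least 35.6-fold lower. The split with library size alone was 1310 and 4004. It turned to 2445 and 1757 with counts summed per locus, 2303 and 1960 with DESeq2, 2003 and 1557 without the filter and 2299 and 2017 with only the 2 groups. The total was 2613 without glucose replicate 2 and 2783 without alfalfa stems replicate 1. Corn stover and alfalfa stems shared 1369 transcripts called higher and 1455 called lower, where independent lists would share 295 and 438, and 107 were opposite.

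The mean of the 3 grasses differed from Avicel in 5558 transcripts of N. californiae, 2738 higher and 2820 lower. Locus1317v1rpkm83.52 was at 341.6 ± 143 CPM over the 8 grass libraries, and Locus1948v1rpkm47.10 rose from 0.915 ± 0.421 CPM on Avicel to 1083 ± 730 CPM on the grasses (log2 fold change 10.12 ± 1.14, edgeR adjusted p = 1.65e-06). Avicel and reed canary grass still shared 946 transcripts called higher and 2018 called lower against glucose, where independent lists would share 307 and 728, and 268 went in opposite directions.

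**Figure D2:**
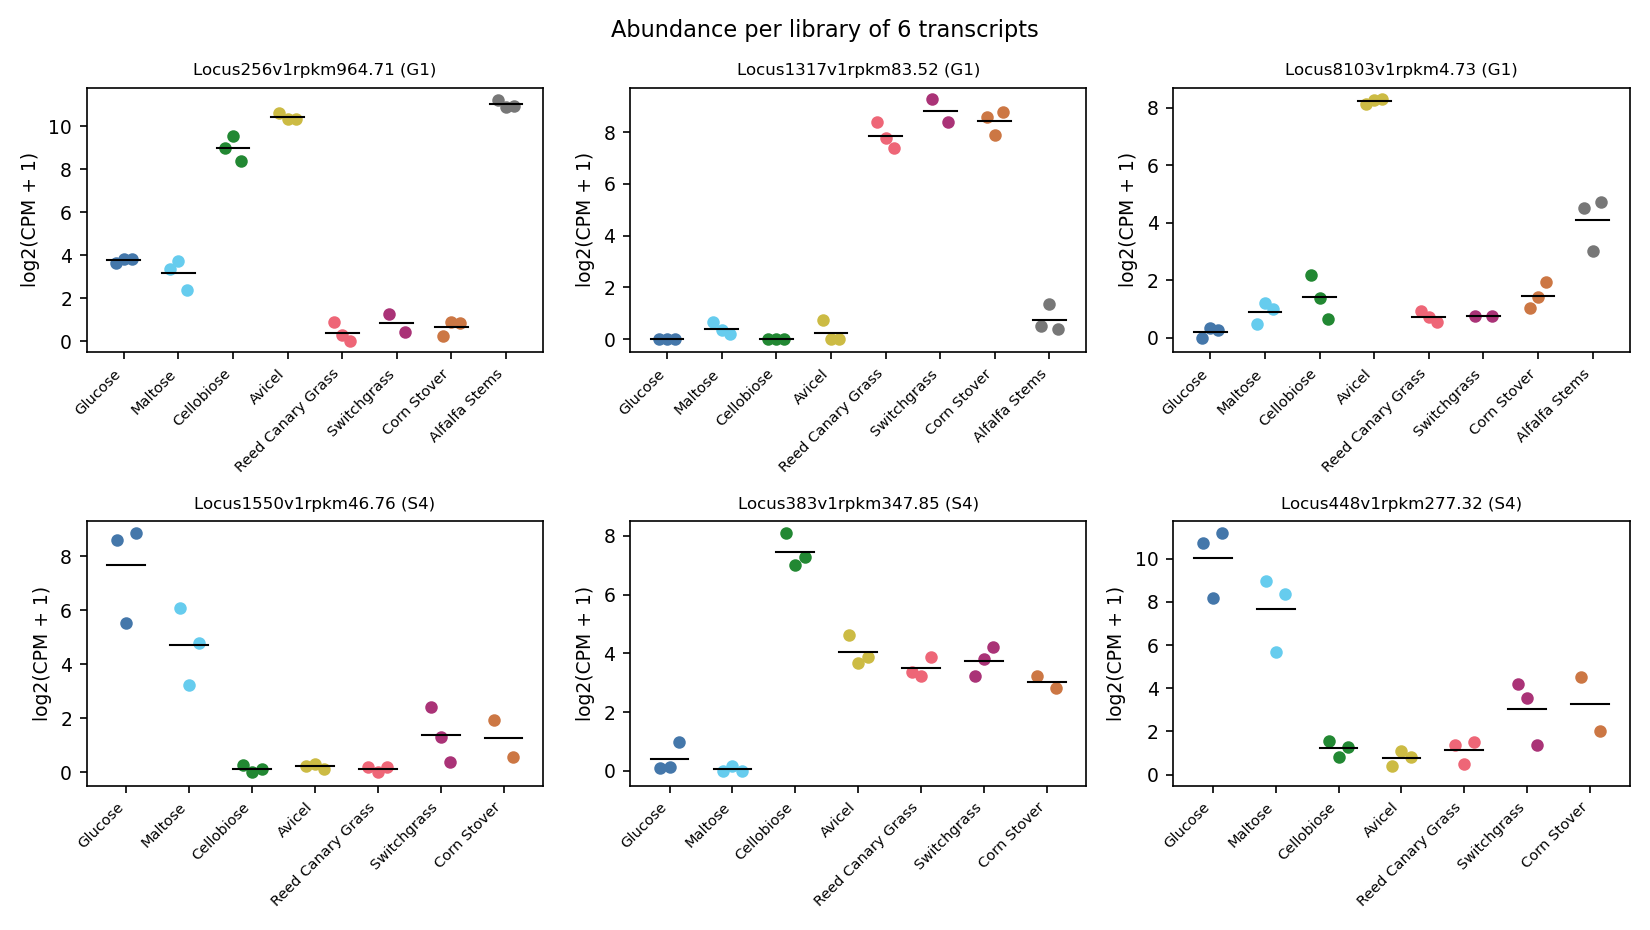
Abundance per library of 6 named transcripts, as log2(CPM + 1) on the vertical axis against carbon source, with points for libraries and bars for means of the plotted values. The upper panels show N. californiae and the lower panels A. robustus. Locus256v1rpkm964.71 averages 2093 CPM on alfalfa stems and 0.581 CPM on the grasses, Locus1317v1rpkm83.52 is on in the grasses alone, and Locus1550v1rpkm46.76 averages 299.3 CPM on glucose and 0.0869 CPM on cellobiose.

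A common set of transcripts answered to every grass in N. californiae. In all, 1548 transcripts were called higher and 1436 lower on each of the 3 grasses, where independent lists would give 49.0 and 121. Alfalfa stems shared 1021 and 924 of them, where an independent list would share 204 and 233. Avicel shared 800 and 809, where it would share 233 and 342, and cellobiose shared 403 and 156, where it would share 78.0 and 33.3. Without cellobiose replicate 3 the cellobiose counts were 340 and 59. The set called higher on every grass held 30.7% ± 1.28 of counts on glucose (SD, n = 3), 55.6% ± 0.774 on reed canary grass, 63.0% ± 0.956 on switchgrass (n = 2) and 62.1% ± 1.69 on corn stover. It was chosen on these grass and glucose libraries, so its share is no independent evidence of direction. Outside the grasses it held 42.6% ± 1.14 on Avicel and 36.5% ± 0.632 on cellobiose. Of the 100 most abundant transcripts, 70 rose and 2 fell on reed canary grass, 75 and 7 on switchgrass, and 72 and 9 on corn stover. With library size alone these were 55 and 17, 63 and 19, and 62 and 21. The whole set called on every grass became 873 higher and 4131 lower with library size alone. Avicel then shared 369 higher and 2788 lower of them, and cellobiose 272 and 295.

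In A. robustus maltose could not be told from glucose by the main test. It called 0 transcripts higher and 1 lower, with 1912 at an unadjusted p under 0.05, while DESeq2 called 676 (192 higher, 484 lower). Without maltose replicate 3, the library that stood apart, the count was again 1. Without glucose replicate 2 the count was 516 (17 higher, 499 lower), without glucose replicate 1 it was 4, and without maltose replicate 1 or 2 it was 0. With library size alone it was 585 (12 higher, 573 lower).

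Cellobiose changed 2419 transcripts against glucose in A. robustus, 1666 higher and 753 lower. Locus383v1rpkm347.85 rose from 0.378 ± 0.518 CPM on glucose to 186 ± 77.6 CPM on cellobiose (n = 3 each), a log2 fold change of 8.99 ± 0.77 (edgeR adjusted p = 3.68e-07), and stood at 16.4 ± 6.55 CPM on Avicel and 12.9 ± 4.54 CPM on switchgrass. Locus2173v1rpkm26.32 rose from 0.260 ± 0.313 to 21.1 ± 12.9 CPM (6.40 ± 0.73, edgeR adjusted p = 7.61e-06). Locus1550v1rpkm46.76 fell from 299.3 ± 223 CPM on glucose to 0.0869 ± 0.0934 CPM (-11.46 ± 1.48, edgeR adjusted p = 7.37e-05), and Locus2484v1rpkm20.77 from 187 ± 82.5 to 0.0826 ± 0.0410 CPM (-11.08 ± 1.36, edgeR adjusted p = 3.25e-05). With DESeq2 size factors the split was 2372 and 594, and with library size alone 2839 and 182. The total was 1148 without glucose replicate 1. Against maltose, cellobiose raised 2784 and lowered 987, and Locus11778v1rpkm0.71 had 19.5 ± 16.7 CPM on maltose and no counts on cellobiose, at least 495-fold lower. The total was 2512 and 2425 without maltose replicate 1 and 2, and the split 7296 and 189 with library size alone.

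Avicel gave A. robustus a response of which about as many calls were shared with other carbon sources as were not. Locus285v1rpkm580.86 rose from 0.699 ± 0.779 CPM on glucose to 242 ± 229 CPM on Avicel (log2 fold change 8.45 ± 1.06, edgeR adjusted p = 1.27e-05), with 6.15 ± 0.373 CPM on reed canary grass. Locus5215v1rpkm5.38 reached 42.9 ± 48.7 CPM on Avicel (8.54 ± 1.12, edgeR adjusted p = 2.79e-05) and stayed under 0.14 CPM on average on each of the other carbon sources. Locus448v1rpkm277.32 fell from 1445 ± 1052 CPM to 0.738 ± 0.398 CPM (-10.85 ± 1.43, edgeR adjusted p = 4.68e-05), and Locus800v2rpkm0.58_PRE from 32.6 ± 30.3 CPM to no counts, at least 330-fold lower. In total 1115 transcripts were called higher and 1478 lower. Of these, 48.2% of the higher and 52.5% of the lower were called on no other carbon source, against 32.7% and 27.2% in N. californiae. This difference between fungi was not tested, and the sets are unlike, since only N. californiae had alfalfa stems among the other carbon sources. The A. robustus calls also include Avicel replicate 1, which stood apart. The split was 363 and 1609 with library size alone. The total was 2302 without Avicel replicate 1, 1525 without glucose replicate 1 and 654 with only the Avicel and glucose libraries in the fit.

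Against cellobiose, Avicel raised 1166 and lowered 2415 transcripts in A. robustus. Locus227v2rpkm128.20 rose from 0.223 ± 0.130 CPM on cellobiose to 84.6 ± 64.0 CPM on Avicel (log2 fold change 8.63 ± 0.82, edgeR adjusted p = 5.65e-07), and Locus2429v1rpkm21.81 fell from 15.4 ± 7.35 to 1.21 ± 1.26 CPM (-3.86 ± 0.64, edgeR adjusted p = 0.000255). The split was 1001 and 3727 with DESeq2, 923 and 3704 with DESeq2 size factors and 183 and 6276 with library size alone. Cellobiose and Avicel shared 400 transcripts called higher and 378 called lower against glucose, where independent lists would share 180 and 108, and 47 were opposite.

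On the grasses A. robustus raised more transcripts than it lowered. Reed canary grass gave 2598 higher and 1676 lower, switchgrass 2790 and 1545, and corn stover 2385 and 1342. Locus5693v2rpkm0.50 rose from 0.296 ± 0.512 CPM on glucose to 12.6 ± 3.98 CPM on reed canary grass (log2 fold change 5.49 ± 1.09, edgeR adjusted p = 0.000735) and 15.8 ± 2.58 CPM on corn stover (n = 2). Locus5028v1rpkm5.78 rose from 0.532 ± 0.922 to 11.4 ± 4.59 CPM on switchgrass (4.48 ± 0.95, edgeR adjusted p = 0.00106). Locus721v1rpkm140.98 rose from 9.05 ± 14.3 to 350 ± 146 CPM on corn stover (5.28 ± 1.19, edgeR adjusted p = 0.0026). Locus1550v1rpkm46.76 and Locus2484v1rpkm20.77, which fell on cellobiose, fell again on reed canary grass, to 0.0912 ± 0.0793 and 0.0590 ± 0.0651 CPM. With DESeq2 the splits were 3475 and 1171, 4225 and 952, and 3214 and 1009. With DESeq2 size factors in edgeR they were 3385 and 1047, 4126 and 851, and 3171 and 834, and with library size alone 2944 and 408, 4118 and 298, and 2641 and 274. Corn stover gave 2147 calls with replicate 1 alone.

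The responses of A. robustus to the 3 grasses overlapped widely. Reed canary grass shared 2344 transcripts called higher and 1184 called lower with switchgrass, where independent lists would share 703 and 251, and 2265 and 1225 with corn stover, where they would share 601 and 218, and 0 went in opposite directions in either pair. The correlation of log2 fold changes was 0.92 and 0.94, where simulated unchanged groups gave 0.52 and 0.46, and the covariance 3.23 and 3.38 against a simulated 0.25 in both. On every grass 2125 transcripts were called higher and 984 lower, against 2524 and 190 with library size alone and 2956 and 681 with DESeq2. Cellobiose shared 1321 and 574 of them, where independent lists would share 343 and 71.8. Avicel shared 327 and 380, where independent lists would share 230 and 141. With library size alone cellobiose shared 2088 and 124 and Avicel 225 and 125. With DESeq2 cellobiose shared 2086 and 478 and Avicel 577 and 316. Each of these lay above the count of independent lists.

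**Figure D3:**
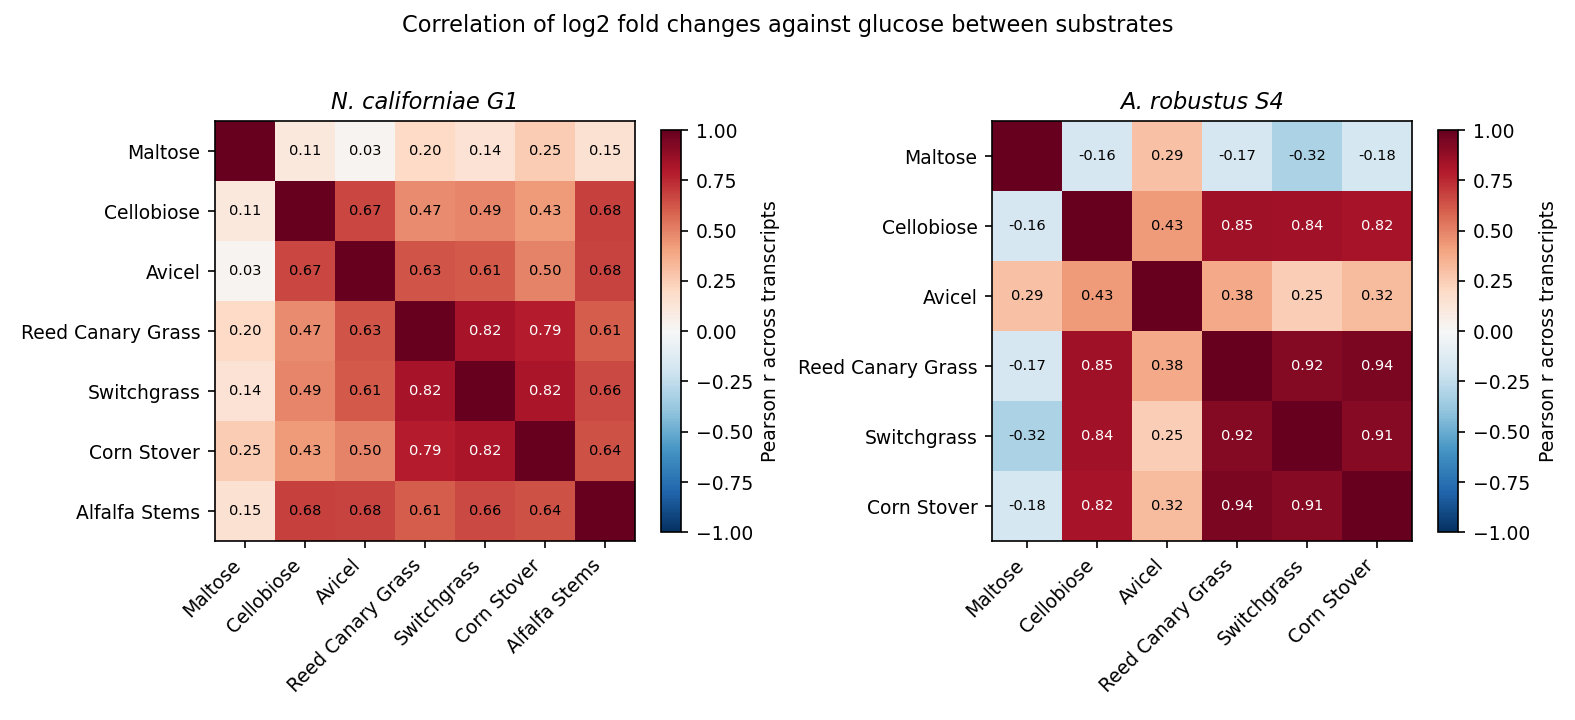
Pearson correlation across tested transcripts of log2 fold changes against glucose for each pair of carbon sources, colored from -1 (blue) to 1 (red), for N. californiae (left) and A. robustus (right). All pairs share the glucose libraries. Sharing simulated glucose libraries alone gave 0.41 to 0.52 in the simulated pairs, where no group was changed. In A. robustus cellobiose correlates with reed canary grass at 0.85 and Avicel with reed canary grass at 0.38, whereas in N. californiae these are 0.47 and 0.63.

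The grasses differed from Avicel in 5609 transcripts of A. robustus, 3417 higher and 2192 lower. Locus757v1rpkm130.85 rose from 2.03 ± 0.683 CPM on Avicel to 523.5 ± 248 CPM over the 8 grass libraries (log2 fold change 8.02 ± 1.34, edgeR adjusted p = 0.00013). Locus4778v3rpkm2.06 fell from 81.2 ± 57.3 to 0.139 ± 0.0943 CPM (-9.28 ± 0.50, edgeR adjusted p = 5.07e-11). The split was 4967 and 1421 with DESeq2, 4898 and 1419 with DESeq2 size factors and 6022 and 324 with library size alone. Of the 100 most abundant transcripts 99 were lower on the grasses than on Avicel and none was higher. With library size alone 21 were lower and 1 higher, and without Avicel replicate 1 61 were lower and 0 higher. This contrast therefore rests on the scaling and in part on 1 library.

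On grass the calls among the abundant transcripts of A. robustus were mostly lower, where those of N. californiae were mostly higher. The difference between the fungi in these calls was not tested. Both lists were chosen by mean CPM on the TMM scale over these same libraries, where a library with a small factor weighs more. In A. robustus the factors were 1.21 to 1.97 on the grasses and 0.78 to 1.05 on glucose. In N. californiae they were 0.64 to 1.03 and 1.13 to 1.36. The smallest factors of A. robustus were 0.18 for maltose replicate 3 and 0.27 for Avicel replicate 1. These libraries, which stood apart from their groups, thus weighed most in the choice of its list. The choice of list may therefore favour lower calls on grass in A. robustus and higher calls in N. californiae. Of the 100 in A. robustus 2 rose and 27 fell on reed canary grass, 0 rose and 37 fell on switchgrass, and 0 rose and 31 fell on corn stover. With library size alone 2 rose on each grass and 21, 26 and 17 fell. Without Avicel replicate 1 in the fit 2 rose and 50 fell on reed canary grass, 1 and 93 on switchgrass, and 2 and 32 on corn stover. The counts thus depend on 1 library outside the grasses. These 100 transcripts held 55.9% ± 2.10 of counts on glucose (SD, n = 3), 43.8% ± 1.75 on reed canary grass, 42.3% ± 0.721 on switchgrass and 45.1% ± 1.94 on corn stover (n = 2). By TPM the shares were 51.4% ± 2.10 on glucose and 45.5% ± 0.996 on reed canary grass. A two-sided exact permutation test of 3 against 3 cannot go below 0.1, the value it gave for reed canary grass. The set called higher on every grass held 1.35% ± 0.457 of counts on glucose and 14.2% ± 0.838 on reed canary grass, and 7.38% ± 0.362 on cellobiose. It was chosen for being low in these glucose libraries, so none of these shares is independent of the choice.

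At 1500000 counts per library, N. californiae had a count for 16752 ± 420 transcripts on glucose (SD, n = 3) and for 14862 ± 831 on the grasses (n = 8), and each grass library lay below each glucose library. A. robustus had a count for 8195 ± 343 transcripts on glucose and for 9841 ± 541 on the grasses, and each grass library lay above each glucose library. The two-sided exact permutation p was 0.00606 in each fungus, the smallest that 8 against 3 libraries can give.

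**Figure D4:**
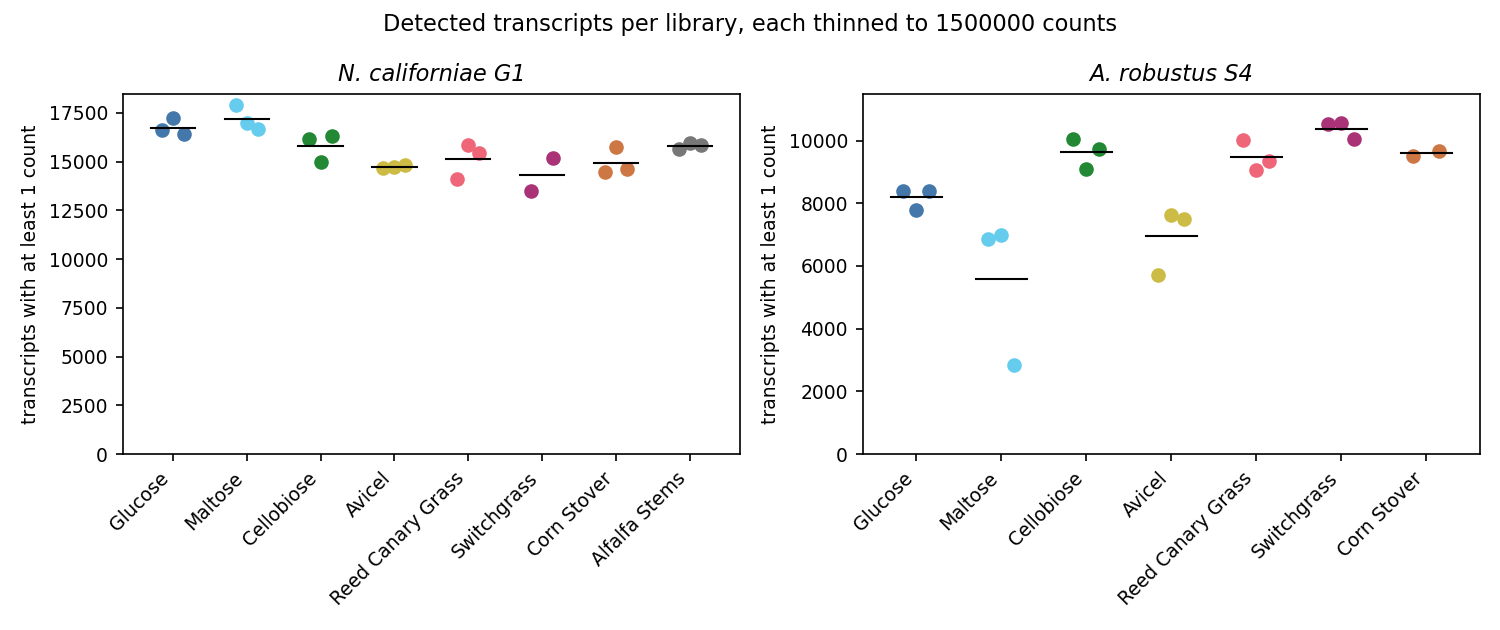
Transcripts with at least 1 count in each library after thinning to 1500000 counts, plotted against carbon source for N. californiae (left) and A. robustus (right), with points for libraries and bars for group means. Glucose libraries lie at 16409 to 17220 and grass libraries at 13514 to 15867 in N. californiae, and at 7799 to 8398 and 9068 to 10558 in A. robustus.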

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

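In the pattern weighed here, the tests of plant RNA and of genomic DNA by the share of transcripts at 0 were chosen or changed after the result was seen. In the test of a few transcripts, set before, the full difference was later recomputed at the count of the rest. The values without maltose replicate 3 were also added later. The family of differences between the fungi held 8 tests, each an exact permutation of the carbon source labels within each fungus, adjusted by Benjamini-Hochberg. The labels of both fungi were permuted together, so a small p speaks against no change in either fungus. It does not by itself show that the changes differ between the fungi.

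The number of transcripts detected at equal depth moved in opposite directions in the 2 fungi on the grasses and on cellobiose, but not on Avicel. From glucose to the grasses it fell by 1890 in N. californiae and rose by 1646 in A. robustus, a difference of 3536 (adjusted exact permutation p = 0.000294), with every grass library on the same side of every glucose library within each fungus. From glucose to cellobiose the difference between the fungi was 2355 (adjusted exact permutation p = 0.0133), again opposite in every library. Within each fungus alone the exact permutation p for cellobiose was 0.1, the smallest that 3 against 3 libraries can give. On maltose the difference between the fungi was -3083 (adjusted exact permutation p = 0.04), where A. robustus includes maltose replicate 3, a library with 2843 detected transcripts. Without that library the difference was -1719 (unadjusted exact permutation p = 0.035), so its size rests in large part on 1 library. On Avicel the number detected fell in both fungi, with a change of -2004 in N. californiae and -1254 in A. robustus (difference 750, adjusted exact permutation p = 0.565). The size of the A. robustus change rests in part on Avicel replicate 1, with 5711 detected transcripts against 7611 and 7502 in replicates 2 and 3. The share of counts held by each library's own 100 most abundant transcripts differed between the fungi by -15.7 percentage points for the grasses (adjusted exact permutation p = 0.000294) and by -12.9 for cellobiose (adjusted exact permutation p = 0.048). For Avicel it was -4.57 (adjusted exact permutation p = 0.565), where A. robustus Avicel replicate 1 held 70.8% against 54.3% and 53.4% in replicates 2 and 3. For maltose it was 14.5 (adjusted exact permutation p = 0.12), and 5.68 without A. robustus maltose replicate 3 (unadjusted exact permutation p = 0.13). Both values therefore rest in part on 1 library each.

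Against a few transcripts taking most of the counts, the grass difference kept 81.2% of its size in N. californiae (both differences at 1300000 counts) and 81.8% in A. robustus (both at 3000000) when the transcripts among the 100 most abundant of any library were left out. Set beside the full difference at 1500000 counts, the shares were 79.7% and 78.8%. RNA carried over from the plants stays open. Over the 8041 transcripts detected in every cellobiose library of A. robustus, grown without plant material, 44.1% of the grass difference was left, between the bounds set for either answer. This test replaced one that could not decide, the rise in detected transcripts on cellobiose itself. Of the grass difference, a further 39.9% lay in transcripts detected in some cellobiose libraries and 15.9% in the 5835 detected in none. Most of the rise was thus in transcripts that at least 1 library without plant material detected. Genomic DNA in the grass libraries of A. robustus stays open. Over 2689 transcripts without counts on glucose, the share at 0 in the deepest switchgrass library was -9.51 percentage points from that of a uniform DNA level, which DNA would allow. The first version of this test, restricted to the 109 transcripts whose length came from at least 20 counts, gave 24.4 points, which DNA would not allow, but that restriction selects expressed transcripts, so the 2 versions together decide nothing. The rank correlation of counts per length between switchgrass libraries was 0.40 (0.39 to 0.43 over the pairs), between the bounds set for either answer. A change in how many genes each fungus expresses on plant material may therefore remain, as may plant RNA or DNA in the libraries.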

How the results depend on the processing

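Library size alone as the scaling, counts summed per locus, and the fits without N. californiae cellobiose replicate 3, A. robustus maltose replicate 3 or A. robustus Avicel replicate 1 in comparisons that do not use them were chosen after seeing the data. No named transcript changed its direction, but the side with more calls turned in 8 comparisons of N. californiae and 1 of A. robustus. The named transcripts were chosen in these same data for the largest folds and for groups that did not overlap. Their stable direction was thus largely fixed by the choice and says little about other transcripts. Of 1076 values of 75 named transcripts under the alternatives, 1021 kept their direction and their call and 55 lost the call, 44 of them with a library left out, 5 without the filter on low counts, 3 with only the compared groups and 3 with the replicate block. Of 364 counts of calls for 22 comparisons, 319 stayed within 1.5 times the main count and 45 did not, 30 of these with a library left out. Where 1 library remained in a group, it was assumed to vary like the other groups. The cause of the moves was not tested, except that fewer libraries give less power. The gene lists were not run, since the identifiers carry no names, and so no set test (camera) or its alternatives.

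With library size alone, maltose against glucose gave 63 calls in N. californiae and 585 in A. robustus, corn stover against glucose 7801 in N. californiae, and in A. robustus cellobiose against maltose 7485 and Avicel against cellobiose 6459. The set called on every grass in N. californiae held 5004. With DESeq2, maltose against glucose gave 72 and 676. With only the compared groups, it gave 0 (626 at an unadjusted p under 0.05 in the edgeR test of all libraries) and 2, cellobiose against glucose 526 in N. californiae and Avicel against glucose 654 in A. robustus. With at least 2-fold required, N. californiae gave 3511 for the grasses against Avicel, 1415 for alfalfa stems against the grasses and 1866 shared by corn stover and alfalfa stems. In A. robustus, maltose against glucose gave 0 with counts summed per locus. The share of the 100 most abundant transcripts, reed canary grass minus glucose, was -5.90 points by TPM and -12.1 by counts.

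With each library left out in turn, counts of calls in N. californiae ranged from 0 to 51 for maltose, 564 to 1453 for cellobiose, 4368 to 6024 for Avicel, 3379 to 5409 for reed canary grass, 3326 to 5870 for switchgrass, 3501 to 5329 for corn stover and 2613 to 4884 for alfalfa stems against glucose. They ranged from 1144 to 2901 for cellobiose against maltose, 1515 to 3810 for Avicel against cellobiose, 4306 to 5856 for the grasses against Avicel and 1278 to 2513 for alfalfa stems against the grasses. In A. robustus they ranged from 0 to 516 for maltose, 1148 to 3310 for cellobiose, 1525 to 3129 for Avicel, 3066 to 4921 for reed canary grass, 3390 to 5076 for switchgrass and 2147 to 4413 for corn stover against glucose, and from 2425 to 4422, 2441 to 4142 and 4990 to 6036 for cellobiose against maltose, Avicel against cellobiose and the grasses against Avicel.

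Replicate numbers did not pair all libraries, but replicate 3 libraries of N. californiae partly deviated together. Deviations from group means correlated between libraries of the same number at -0.37 to 0.42 in N. californiae, with 27 of 77 pairs over 0.1 and 8 of 23 libraries closest to their own number. In A. robustus they correlated at -0.23 to 0.35, with 16 of 57 pairs and 9 of 20 libraries. In N. californiae the deviation of glucose replicate 3 correlated at 0.37 with that of maltose replicate 3 and at 0.42 with cellobiose replicate 3. With replicate 3 of reed canary grass, corn stover and alfalfa stems it correlated at 0.16, 0.18 and 0.16, but with Avicel replicate 3 at -0.01. A block on the number moved 1 count by over 1.5 times, A. robustus maltose against glucose, to 2. In N. californiae it turned the larger side of cellobiose against maltose, to 1289 higher and 1908 lower. It also turned that of alfalfa stems against the grasses, to 1263 and 1214. Depth may limit the transcripts near the filter in both fungi, which was not tested.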

Other observations

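The contrasts of the grasses with cellobiose and between grasses, the set of transcripts that switch between substrates, and in the library patterns the tests of maltose as the cause, of an outside source, of both swaps and of a shared deviation were chosen after the result was seen. The verdicts of 2 tests of the library patterns were also changed after their values were seen. The test of maltose was set to undecided. In the test of a mixture, a floor of 20 transcripts that had left it undecided was dropped, because the prediction written beforehand held no floor.

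In A. robustus the response to cellobiose resembled the response to grass more than the response to Avicel did. Of the transcripts called higher on cellobiose 79.3% were called higher on every grass, against 29.3% of those called higher on Avicel, and in N. californiae these were 54.0% and 35.9%. In A. robustus they were 73.5% and 62.0% with library size alone and 81.9% and 47.2% with DESeq2. Without Avicel replicate 1 they were 77.6% and 40.7%. The size of the gap thus depends on the scaling and in part on 1 library. The correlation of log2 fold changes with reed canary grass across transcripts was 0.85 for cellobiose and 0.38 for Avicel in A. robustus, and 0.84 and 0.42 with library size alone. In N. californiae it was 0.47 and 0.63, and the first became 0.27 without cellobiose replicate 3. Sharing simulated glucose libraries alone gave 0.51 and 0.52 in A. robustus and 0.49 for both in N. californiae, so neither the 0.38 nor the 0.47 shows a resemblance by itself. The simulated groups hold no change, so their correlations rest on noise alone, and the covariances are the closer comparison. The covariance was 2.47 for cellobiose and 1.28 for Avicel in A. robustus (simulated 0.25 for both), and 0.79 and 1.84 in N. californiae (simulated 0.18 for both). The difference between the fungi was not tested. The grasses differed from cellobiose in 896 transcripts of A. robustus, 547 higher and 349 lower, while they differed from Avicel in 5609. The first count was 260 with library size alone and 2662 without maltose replicate 3 and Avicel replicate 1. In N. californiae the counts were 4283 and 5558, but 6717 and 5331 with library size alone, so their order depends on the scaling.

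Few transcripts were called between the grasses. In A. robustus edgeR called 0 transcripts between switchgrass and reed canary grass (751 at an unadjusted p under 0.05), 0 between corn stover and reed canary grass (143) and 1 between corn stover and switchgrass (627). In N. californiae it called 128 (1940 at an unadjusted p under 0.05), 290 (2799) and 0 (1307) in the same order, and 220, 478 and 2 with library size alone, so smaller differences may have been missed. DESeq2 was not run on these contrasts. A set of 125 transcripts of N. californiae was called at least 8-fold lower on the grasses than on both Avicel and alfalfa stems, where independent lists of 275 and 185 would share 3.44, and 158 were at least 8-fold higher, where independent lists would share 5.59. Both contrasts use the grass libraries, so part of the excess may come from them, and alfalfa stems against the grasses gave 1415 calls when at least 2-fold was required.

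Maltose replicate 3 of A. robustus stood apart. In it 22 transcripts, each over 10 times its highest TPM elsewhere, held 57.3% of counts. Against these transcripts as the whole cause, the rest of the library at equal counts detected 49.2% as many transcripts as the lower of the other 2 maltose libraries. Whether maltose plays a part cannot be told from these transcripts: they held at most 0.309% of counts in those 2 libraries, but they were chosen for being low elsewhere. One outside source present in every library in different amounts may account for part of it. Over the 6 of these transcripts with at least 30 counts in every library, the SD of the log2 ratio to the other libraries was 0.26 (median over libraries). Such a steady ratio does not tell an outside source from transcripts of the fungus that vary together. Among the 6, Locus13975v1rpkm0.38 and Locus13975v2rpkm0.24 are versions of 1 locus. Of the 22, 11 had under 30 counts in all other libraries together.

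Cellobiose replicate 3 of N. californiae lay closer to Avicel, at 0.91 in rank correlation, than to the other cellobiose libraries, at 0.88 to 0.89. This was not particular to Avicel, since alfalfa stems replicates 1 and 3 stood at 0.91 and 0.92. Against a swap with an Avicel library, the lowest correlation between Avicel libraries exceeded the highest between an Avicel and a cellobiose library by 0.0439. Against a swap with an alfalfa stems library, the lowest correlation between those exceeded the highest with cellobiose replicate 1 or 2 by 0.0309. Against a mixture with Avicel RNA in a single share, the log2 ratio to Avicel had an interquartile range of 7.29, over the bound of 2 set beforehand, across 8 transcripts near absent in the other cellobiose libraries. Of these, 4 had at most 1 count in this library and at least 104 in each Avicel library, and the other 4 had 266 to 999 counts. A mixture with alfalfa stems RNA cannot be told apart, since only 2 transcripts could be used where 5 were required beforehand (interquartile range 0.13). A deviation shared with libraries of 3 other substrates at over 0.3 (glucose, reed canary grass and switchgrass) may be a candidate explanation. Glucose replicate 3 and reed canary grass replicate 3 carry the same replicate number, at 0.42 and 0.34, but reed canary grass replicate 2 and switchgrass replicate 2, at 0.32 and 0.41, do not, and Avicel replicate 3 stood at 0.02, so the number does not account for all of it.

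Each comparison of 3 against 3 libraries has 10 splits, the real one included, too few for a share under 0.05. In N. californiae the real split gave 1089 calls and the highest other 0 for cellobiose against glucose, 5754 and 0 for Avicel, 5093 and 0 for reed canary grass, 4942 and 0 for corn stover, 4347 and 0 for alfalfa stems, 2186 and 0 for cellobiose against maltose and 3027 and 0 for Avicel against cellobiose, so that 1 of 10 splits was as large in each. For maltose against glucose 2 of 10 splits gave as many calls, the real one 17 and the highest other 20. In A. robustus 1 of 10 was as large in each of cellobiose against glucose (2419, highest other 2), Avicel (2593, highest other 121), reed canary grass (4274, highest other 0), switchgrass (4335, highest other 0), cellobiose against maltose (3771, highest other 0) and Avicel against cellobiose (3581, highest other 0). For maltose against glucose in A. robustus 5 of 10 splits gave as many as the real 1 call, and the highest other gave 550, with maltose replicates 1 and 2 and glucose replicate 2 on the same side, which points to a structure of the samples beyond the carbon source. For the pooled comparisons 1 of 30 drawn splits was as large, the real one, which is the smallest share that 30 splits can give. The other splits mix carbon sources within a group, which widens the spread and leaves few calls. Their low counts speak against chance in how single libraries fell into the groups, but cannot exclude it or a dependence between libraries of a group. The grasses against Avicel gave 5558 in N. californiae (highest other 76) and 5609 in A. robustus (highest other 596), and alfalfa stems against the grasses gave 2276 (highest other 153).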
